A study of Homo sapiens with 36 samples.

How the data were processed

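RNA sequencing was analysed for 36 libraries of human induced pluripotent stem cells and their mesodermal derivatives. Per the labels' protocols, total RNA was purified with an RNeasy kit, and 200 to 300 ng entered the TruSeq Stranded mRNA LT kit, which selects polyadenylated RNA. The established lines 201B7 and 1231A3 were each sampled at 6 stages, with 3 experiments per stage and line. Per the labels' protocols, primitive streak cells were made in 24 h with bFGF (20 ng/ml), Activin A (50 ng/ml) and the Wnt pathway activator CHIR99021 (10 µM). Presomitic mesoderm followed in 24 h with the activin receptor inhibitor SB431542 (10 µM), CHIR99021 (3 µM), bFGF (20 ng/ml) and the BMP receptor inhibitor LDN193189 (250 nM). Somite cells were made in a further 24 h with the FGF receptor inhibitor PD173074 (100 nM) and the Wnt inhibitor XAV939 (1 µM). From there, 72 h with the hedgehog agonist SAG (100 nM) and LDN193189 (600 nM) gave sclerotome. Dermomyotome was made in 48 h with BMP4 (50 ng/ml), CHIR99021 (3 µM) and the hedgehog inhibitor GDC0449 (150 nM).

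The deposited values are FPKM, 1 column per library. Per the submitters' processing notes, reads were converted with bcl2fastq 2.17.1.14, trimmed with cutadapt 1.14 and aligned to hg38 with HISAT2 2.1.0, and FPKM came from Cuffdiff of Cufflinks 2.2.1. The options, the gene annotation, the use of strand and any scaling between libraries are not given in the sources used here. The table held 58023 genes, of which 57419 (99.0%) matched an identifier of GENCODE release 29, whose GRCh38 coordinates are given. Y-linked genes and genes of X inactivation (575 in all) were removed, leaving 57448. Symbols shared by several genes (1717 entries) were kept under their own identifiers. Overlapping genes, genes with near-identical copies and short RNAs, which a poly(A) kit catches poorly, are reported as uncertain.

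FPKM tables carry no read totals. The depth of each library was therefore estimated from the spacing of its lowest values, because single fragments give values in whole steps. It came to about 7.3 to 49.4 M fragments (ratio 6.77). Values under 0.15 of the same gene were also compared between each library and iPSC 201B7 replicate 1. Of their ratios, 53.3% to 64.9% lay at the most frequent ratio or differed from it by a ratio of small whole numbers. A single fragment weighs more in a shallow library, so low values were least precise in dermomyotome 201B7 replicate 2, the shallowest. No library was identical to another (0 of 630 pairs, highest r 0.985).

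Genes with FPKM of at least 1 in at least 3 libraries were tested (18644 genes). Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 12 groups, an intensity trend in the prior variance and 24 residual degrees of freedom. Stage contrasts averaged both lines with equal weight. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 together with an absolute log2 change of at least 1. The stage comparisons followed the protocol: PS against iPSC, PSM against PS, SM against PSM, DM against SM, SCL against SM and SCL against DM. A step was called line-dependent from the interaction contrast, the step in 1231A3 minus the step in 201B7. The lines were compared as 1231A3 minus 201B7, averaged over stages. A gene was called stage-enriched when it was called higher in that stage against each of the other 5. P-values measure the spread between samples.

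The design, the comparisons, 36 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Lists covered pluripotency, primitive streak, presomitic mesoderm, vertebrate cyclic genes, somite, dermomyotome, sclerotome, skeletal myogenesis, cartilage matrix, and fibroblast and tendon. Other cell types were covered by lists for neural, neural crest, endoderm, lateral plate and cardiac, intermediate mesoderm, endothelium and blood, amnion and trophoblast, epithelial and mesenchymal genes. Signalling was covered by targets of Wnt, FGF-ERK, BMP, hedgehog and NODAL-activin, by the Notch pathway, retinoic acid and HOX groups. Further lists held proliferation, p53 and stress, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, mitochondrially encoded and ribosomal protein genes. HOX groups 10 to 13 had too few tested members and were not tested, which left 35 lists. Some genes stand in more than 1 list, for example CER1 in endoderm and NODAL-activin, FOXC2 in somite and sclerotome, and PAX3 in somite and dermomyotome. Each list was tested in 6 comparisons with limma's camera, which compares members with all other genes, at a preset correlation between genes of 0.01, adjusted over 210 tests. Camera with an estimated correlation and limma's fry stood beside it.

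Named genes were the 8 largest called rises and falls per stage comparison whose 6 libraries of each stage did not overlap, with a mean of at least 5 FPKM in the higher stage. Clone, LOC, LINC, antisense and microRNA names were passed over. Up to 4 called members of each discussed list with the largest change were added, and any member of the first 7 lists. For each line-dependent step and for the lines, the rule took 4 genes per direction with at least 5 FPKM in a group, and 6 genes per stage for stage enrichment. A few genes outside the rule are named as chosen after their values were seen. Some genes that the rule took are not reported here.

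The fit was tested on simulated data with 18644 genes, of which 40 per fold size changed. For PS against iPSC it called 0.0% of changes of 0.75 on the log2 scale, 42.5% of changes of 1 and 100.0% of changes of 1.5 or more, with 2 of 18444 unchanged genes called. For the line-dependent step from iPSC to PS it called 45.0% at 1, 80.0% at 1.5, 90.0% at 2 and 100.0% at 3, with 4 unchanged genes called. For the lines it called 42.5% at 1 and 100.0% at 1.5, and for PS-enriched genes 15.0% at 1 and 95.0% at 1.5. With nothing changed, 0 genes were called in each of the 6 stage comparisons. The simulated noise was independent between genes and libraries and held no deviation shared by an experiment. Changed genes were drawn from those with a mean log2(FPKM + 1) above 2. These rates may therefore be better than those of the real data.

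Alternatives were other pseudocounts, filters, scalings and thresholds, limma's treat (a test against a log2 change of 1), each line alone, the compared stages alone, an experiment block, and each library left out in turn. Leaving out experiment 1 and keeping protein-coding genes only were added after the data were seen. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9. Raw reads were not used here.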

Results

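Polyadenylated RNA was measured in 36 libraries of human induced pluripotent stem cells (iPSCs) taken stepwise toward paraxial mesoderm, the embryonic tissue that forms the somites. The lines 201B7 and 1231A3 were each collected as undifferentiated iPSC, primitive streak (PS), presomitic mesoderm (PSM), somite (SM), dermomyotome (DM) and sclerotome (SCL) cells, 3 libraries in each of 12 groups. Dermomyotome, the source of skeletal muscle and dorsal dermis, and sclerotome, the source of vertebrae and ribs, were alternative products of SM. None of the libraries was an untreated or time-matched control of a step. Effects of the added factors therefore cannot be told apart from those of time and of the removal of earlier factors. Values are FPKM, by definition fragments scaled to transcript length and to the mapped fragments of the library. Whether a further scaling between libraries was applied is not given in the sources used here. The estimated depth was about 7.3 to 49.4 M fragments per library, lowest in DM 201B7 replicate 2 and highest in PSM 201B7 replicate 3. The FPKM values of a library summed to between 748398 and 966486, and 14250 to 15213 genes reached 1 FPKM. Changes are differences of log2(FPKM + 1) between stage means of both lines, over 18644 tested genes. Levels are given as mean ± SD over the 6 libraries of a stage, or the 3 of a group. P-values measure the spread between samples, which the series describes as 3 independent ones per stage and line. Positions are on GRCh38.

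Libraries grouped by stage and, within a stage, by line. All 36 libraries correlated most strongly with a library of their own group. The median Pearson r was 0.976 (0.961 to 0.985) within groups, 0.957 (0.940 to 0.975) between the lines at the same stage and 0.906 (0.847 to 0.961) between stages. The range between stages overlapped that between the lines.

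**Figure D1:**
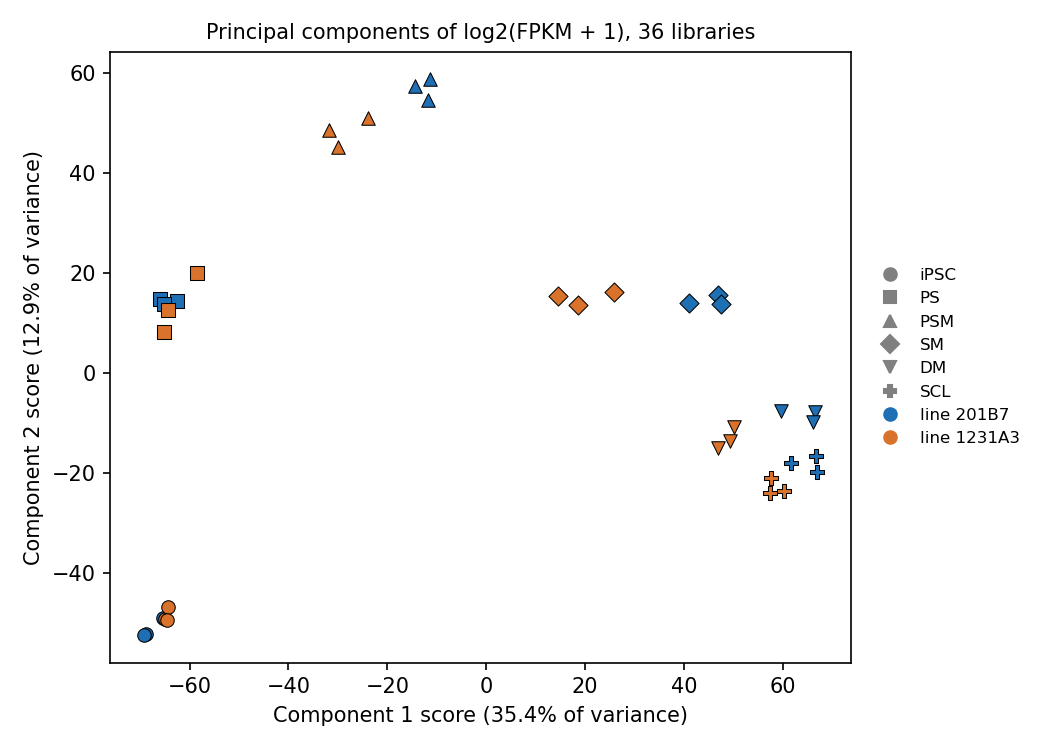
Scores of the 36 libraries on the first and second principal components of log2(FPKM + 1), which held 35.4% and 12.9% of the variance; each point is 1 library, its shape the stage and its colour the line. The first component ran from -69.18 in an iPSC library to 66.83 in an SCL library, and PSM libraries had the highest scores on the second, 45.29 to 58.76.

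The step from iPSC to PS asked which genes change over a day with activin, FGF and Wnt activation. Primitive streak genes rose: MIXL1, a homeobox factor of the streak, rose from 1.54 ± 0.585 to 1808 ± 259.7 FPKM (n = 6 each), T (brachyury) reached 292 ± 107 FPKM and EOMES, a T-box factor of mesendoderm, 142 ± 39.4 FPKM. The Wnt antagonists DKK1 and DKK4 rose alongside, to 1056 ± 497 and 591 ± 141 FPKM. SOX2, a core pluripotency factor that also marks neural progenitors, fell from 88.4 ± 8.40 to 9.91 ± 9.26 FPKM, while POU5F1, another core factor, stood at 1054 ± 166 in iPSC and 772 ± 64.5 in PS.

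The largest rises on the log2 scale were MIXL1 at 9.50 (SE 0.247, limma adjusted p = 5.15e-22; ENSG00000185155.11, chromosome 1, 226223618 to 226227054) and DKK1 at 9.16 (SE 0.305, limma adjusted p = 1.10e-19; ENSG00000107984.9, chromosome 10, 52314296 to 52318042). DKK4 rose by 9.05 (ENSG00000104371.4, chromosome 8, 42374068 to 42377232), T by 7.76 (ENSG00000164458.9, chromosome 6, 166157656 to 166168700), SP5 by 7.66, EOMES by 6.96 (ENSG00000163508.12, chromosome 3, 27715949 to 27722711), EVX1 by 6.04 and GAD1 by 5.63. The largest falls were RMST_10 at -4.91, NPTX1 at -4.57, SPTSSB at -4.48, SORBS2 at -3.93, TRIML2 and APELA at -3.86, the Wnt antagonist SFRP1 at -3.83 and SOX2 at -3.52 (SE 0.277, limma adjusted p = 2.39e-11; ENSG00000181449.3, chromosome 3, 181711924 to 181714436). RMST_10 is a part of a long non-coding RNA counted on its own, so its level is uncertain. All 16 genes separated the 6 libraries of each stage, which the rule for naming them required.

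All 15 tested primitive streak genes rose (median 4.57, camera adjusted p = 3.44e-27), among them the organizer gene GSC by 4.81 and the caudal factor CDX1 by 5.60. Of 13 Wnt targets 12 rose, including the Wnt effector LEF1 by 4.66 (camera adjusted p = 2.85e-17). Of 10 mesenchymal genes 5 rose, with the cadherins CDH11 by 3.40 and CDH2 by 2.87 and the transcriptional repressor SNAI1 by 2.69 (camera adjusted p = 1.09e-08). The call of each of these 3 lists held with an estimated correlation. Of 16 pluripotency genes 7 fell, including FOXD3 at -3.31 and PRDM14 at -2.62, while POU5F1 at -0.44 and NANOG at -0.47 were not called (camera adjusted p = 3.12e-07, adjusted p = 0.0771 with an estimated correlation). NODAL-activin targets rose for 5 of 10, NODAL itself by 4.51 (camera adjusted p = 7.00e-05, adjusted p = 0.106 with an estimated correlation). BMP targets rose for 5 of 11, MSX1 by 4.27 (camera adjusted p = 0.000191, adjusted p = 0.200 with an estimated correlation), and endoderm genes for 4 of 7 with 1 lower (camera adjusted p = 0.0338, adjusted p = 0.123 with an estimated correlation).

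Of 16 presomitic genes 10 rose already at this step and 1 fell (camera adjusted p = 2.27e-08, adjusted p = 0.0725 with an estimated correlation). PS 1231A3 replicate 2 stood apart from its group there. It held MSGN1, a presomitic transcription factor, at 44.2 FPKM against 4.71 and 3.31 in the other two libraries of the group. HES7, the clock repressor, was at 18.5 against 0.280 and 0.581. In PS 201B7 the mean of MSGN1, 31.8 FPKM, was nearer to this library, whereas that of HES7 was 1.835. Without that library HES7 (1.24) and the somite list members FOXC1 (1.26) and ALDH1A2 (1.19) were no longer called, at 0.62, 0.88 and 0.69, and the count of called genes was 1339. Vertebrate cyclic genes, which oscillate with the segmentation clock in other vertebrates, rose for 9 and fell for 3 of 20 (camera adjusted p = 0.000212, adjusted p = 0.238 with an estimated correlation).

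In all, 768 genes were called higher and 588 lower in PS than in iPSC, 1356 of 18644 (7.3%), of which 1354 moved the same way in both lines. Here and at each later step, the call rested on the mean of both lines and a minimum change. That selection favours such agreement, so it is no independent replication, and the share over all genes was not computed. In this and every other comparison, the counts adjusted over the list alone equalled those over all genes tested for all 35 lists. The count was 2545 with a pseudocount of 0.1 and 599 when tested against a log2 change of 1.

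**Figure D2:**
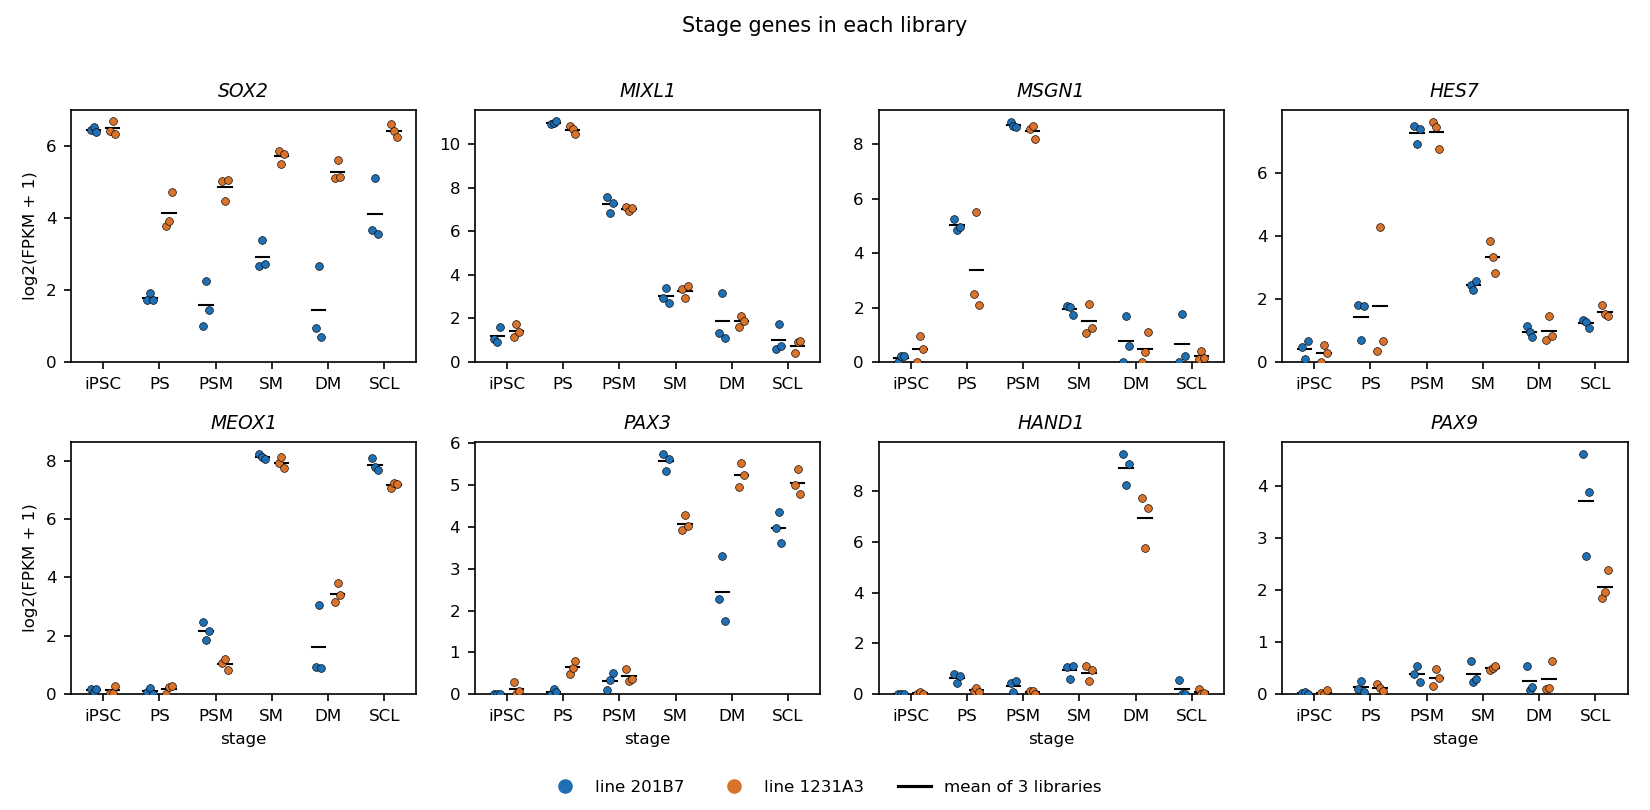
Levels of 8 stage genes, log2(FPKM + 1) on the vertical axis and stage on the horizontal axis; each point is 1 library (blue 201B7, orange 1231A3) and each bar the mean of 3. MIXL1 peaked in PS at 1808 FPKM, and MEOX1 in SM at 264 FPKM.

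The step from PS to PSM asked what changes when activin and BMP receptors are blocked while FGF and, at a lower dose, the Wnt activator continue. The clock repressor HES7 went from 4.14 ± 7.08 to 156 ± 34.8 FPKM and MSGN1 from 24.6 ± 17.0 to 389 ± 54.3 FPKM (n = 6 each). The T-box factor TBX6 reached 249 ± 61.8 FPKM, the Notch ligand DLL1 117 ± 28.7 and LFNG, a glycosyltransferase that modulates Notch, 163 ± 67.5. NODAL, a ligand that sustains the streak, fell from 302 ± 116 to 2.31 ± 1.51 FPKM, and NANOG, a pluripotency factor, from 33.8 ± 13.4 to 2.69 ± 2.47.

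The largest rises were CXCR4, a chemokine receptor, at 5.73 (SE 0.304, limma adjusted p = 7.21e-15; ENSG00000121966.6, chromosome 2, 136114349 to 136118165) and HES7 at 5.67 (SE 0.390, limma adjusted p = 1.72e-12; ENSG00000179111.8, chromosome 17, 8120590 to 8124092). They were followed by HOXB1 (5.63), DLL1 (5.24; ENSG00000198719.8, chromosome 6, 170282206 to 170306565), PPP1R17 (5.13), ALDH1A2, which makes retinoic acid (5.10), LFNG (4.84) and HOXB2 (4.58). Among the largest falls were DKK4 at -8.41 (SE 0.139, limma adjusted p = 1.96e-26), the NODAL and Wnt antagonist CER1 at -7.08, NODAL at -6.54 (ENSG00000156574.9, chromosome 10, 70432315 to 70447951), CYP26A1, which degrades retinoic acid, at -5.44, the NODAL co-receptor TDGF1 at -4.54, CD48 at -4.48 and CALCR at -4.17.

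Of 10 NODAL-activin targets 9 fell (camera adjusted p = 1.13e-16), and of 10 mesenchymal genes 7 rose, SNAI2 by 3.54 and the filament protein VIM by 2.51 (camera adjusted p = 2.83e-07). Of 7 endoderm genes 3 fell (camera adjusted p = 0.00362). These 3 calls held with an estimated correlation. Of 13 genes of HOX groups 1 to 5, 10 rose, HOXA3 by 3.46 (camera adjusted p = 1.73e-11, adjusted p = 0.0820 with an estimated correlation), whereas HOX groups 6 to 9 had a median of 0.24 over 4 genes (camera adjusted p = 0.582). Notch pathway genes rose for 8 of 17 with 1 lower, DLL3 by 4.18 (camera adjusted p = 5.80e-06, adjusted p = 0.105 with an estimated correlation). Presomitic genes rose for 9 and fell for 2 of 16, with MSGN1 at 4.39, TBX6 at 4.22 and CYP26A1 falling (camera adjusted p = 0.00168, adjusted p = 0.302 with an estimated correlation). FGF-ERK targets rose for 5 of 14, the phosphatase DUSP6 by 2.09 (camera adjusted p = 0.00284, adjusted p = 0.351 with an estimated correlation). Cyclic genes rose for 8 and fell for 5 of 20 (camera adjusted p = 0.0258, adjusted p = 0.459 with an estimated correlation). Wnt targets fell for 4 and rose for 1 of 13, DKK1 by -2.18 and LEF1 by 1.98 (camera adjusted p = 0.285).

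Primitive streak genes fell for 11 of 15 and rose for 2, WNT8A by 4.17 and WNT3A by 3.53, while MIXL1 changed by -3.67 and EOMES by -3.96 (camera adjusted p = 6.73e-07, adjusted p = 0.0887 with an estimated correlation). Epithelial genes fell for 8 of 13, the adhesion molecule EPCAM by -2.13 (camera adjusted p = 6.27e-06, adjusted p = 0.126 with an estimated correlation), and pluripotency genes for 7 of 16, POU5F1 by -1.33 (camera adjusted p = 2.70e-05, adjusted p = 0.141 with an estimated correlation). BMP targets fell for 4 of 11 (camera adjusted p = 0.0115, adjusted p = 0.361 with an estimated correlation). Somite genes rose for 6 of 14, the forkhead factor FOXC1 by 4.22 (camera adjusted p = 0.00305, adjusted p = 0.364 with an estimated correlation).

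There were 845 genes called higher and 579 lower in PSM than in PS, 1424 in all, of which 1419 moved the same way in both lines. With a pseudocount of 0.1 the count was 2686, and 576 passed the test against a log2 change of 1. PSM 201B7 replicate 3 held ZFP42, a pluripotency list gene, at 30.8 FPKM against 0 to 1.89 in the other 17 libraries of 201B7, and without it 1414 genes were called.

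The step from PSM to SM asked what follows when FGF and Wnt signalling are inhibited. Of 14 somite genes 12 rose within a day, while presomitic genes moved both ways. RIPPLY1, a repressor of presomitic genes, went from 0.0382 FPKM to 207 ± 21.4, MEOX1, a somite homeobox factor, from 2.31 ± 1.51 to 264 ± 30.8, and TCF15, a factor of epithelial somites, from 2.48 ± 0.400 to 132 ± 31.9 (n = 6 each). MSGN1 dropped from 389 ± 54.3 to 2.42 ± 0.975 FPKM, T from 137 ± 29.9 to 2.12 ± 1.40 and HES7 from 156 ± 34.8 to 6.92 ± 3.61. LFNG, a presomitic and cyclic list member, stood at 163 ± 67.5 FPKM in PSM and 236 ± 50.5 in SM, a difference of 0.61 that was not called.

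RIPPLY1 had the largest rise at 7.65 (SE 0.117, limma adjusted p = 2.81e-27; ENSG00000147223.5, chromosome X, 106900063 to 106903335), followed by MEOX1 at 6.44 (SE 0.221, limma adjusted p = 4.30e-19; ENSG00000005102.12, chromosome 17, 43640388 to 43661954). CER1 rose by 5.32, TCF15 by 5.23, SFRP5 by 4.79, FOXL1 by 4.69, PAX3, a paired box factor of the dorsal somite, by 4.45 (ENSG00000135903.18, chromosome 2, 222199888 to 222298996) and IGFBP5 by 4.40. The largest falls were MSGN1 at -6.87 (SE 0.390, limma adjusted p = 1.96e-14; ENSG00000151379.3, chromosome 2, 17816496 to 17817101), TAC1 at -6.24, T at -5.57, RSPO3, which strengthens Wnt signals, at -5.49, WNT3A at -4.96, SPRY4 at -4.95, PCSK1 at -4.94 and WNT5B at -4.82.

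Of 14 somite genes 12 rose, including FOXC2 by 3.94 (camera adjusted p = 1.23e-15). FOXC2 and FOXL1 are neighbours on chromosome 16, 86566829 to 86569728 and 86576368 to 86582160. Of 14 FGF-ERK targets 12 fell: DUSP6 changed by -4.35, from 272 ± 65.7 to 13.8 ± 7.11 FPKM, and the immediate early factor EGR1 by -4.02 (camera adjusted p = 1.85e-15). Primitive streak genes fell for 9 of 15 (camera adjusted p = 1.13e-08), and Wnt targets for 8 of 13, with CDX1 at -4.37, SP5 at -3.43 and DKK1 at -3.24 (camera adjusted p = 1.03e-05). All 4 of these calls held with an estimated correlation.

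Presomitic genes fell for 10 and rose for 5 of 16: HES7 changed by -4.38 and TBX6 by -3.38, but MESP2, which sets segment borders, rose by 2.90, the protocadherin PCDH8 by 2.79 and RIPPLY2 by 1.67, though it was -0.46 in 201B7 alone (camera adjusted p = 0.0193, adjusted p = 0.435 with an estimated correlation). Cyclic genes fell for 10 and rose for 4 of 20, among the latter the Notch effector HEY1 (camera adjusted p = 0.0338, adjusted p = 0.492 with an estimated correlation). Dermomyotome genes rose for 4 and fell for 1 of 11 (camera adjusted p = 0.00406, adjusted p = 0.166 with an estimated correlation). Sclerotome genes rose for 4 of 11, COL2A1, a cartilage collagen, by 3.02 (camera adjusted p = 0.00550, adjusted p = 0.330 with an estimated correlation). Genes of HOX groups 1 to 5 fell for 5 and rose for 1 of 13, HOXB1 by -3.83 (camera adjusted p = 0.00918, adjusted p = 0.507 with an estimated correlation). Epithelial genes fell for 8 of 13 (camera adjusted p = 0.00168, adjusted p = 0.291 with an estimated correlation).

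SM had 723 genes called higher and 810 lower than PSM, 1533 in all, with 1523 moving the same way in both lines. A pseudocount of 0.1 gave 2768, and the test against a log2 change of 1 gave 668.

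The step from SM to DM asked which genes change over 48 h with BMP4 and Wnt activation and hedgehog signalling blocked. All 11 BMP targets rose. PRRX1, a homeobox factor of limb mesenchyme, went from 0.491 ± 0.594 to 269 ± 129 FPKM and HAND1, a factor of lateral plate and heart, from 0.875 ± 0.324 to 328 ± 248 (n = 6 each). Somite genes fell, MEOX1 from 264 ± 30.8 to 6.55 ± 4.80 FPKM and TCF15 from 132 ± 31.9 to 3.80 ± 2.2. Dermomyotome genes moved in both directions: ALX4 rose from 0.0695 to 12 ± 1.54 FPKM, PAX7 reached 2.94 ± 2.28 FPKM, and PAX3 stood at 31.4 ± 17.6 in SM and 21.2 ± 18.4 in DM.

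PRRX1 had the largest rise at 7.42 (SE 0.213, limma adjusted p = 5.96e-21; ENSG00000116132.11, chromosome 1, 170662728 to 170739419) and HAND1 followed at 7.04 (SE 0.220, limma adjusted p = 4.48e-20; ENSG00000113196.2, chromosome 5, 154474972 to 154478264). MSX2, a homeobox target of BMP, and NRP1 rose by 5.72, the BMP pseudoreceptor BAMBI and NPPB by 5.70, the matrix genes TNC by 5.68 and COL3A1 by 5.39. RIPPLY1 had the largest fall at -6.83 (SE 0.117, limma adjusted p = 3.06e-26), followed by CER1 at -5.93, MEOX1 at -5.51 (SE 0.221, limma adjusted p = 1.07e-17), TCF15 at -4.89, LFNG at -4.51, WNT8A at -4.50, FOXL1 at -4.19 and DLL3 at -4.06.

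All 11 BMP targets rose, with MSX1 at 4.40 and the BMP effector ID2 at 4.37 (camera adjusted p = 3.92e-16). Of 12 lateral plate and cardiac genes 10 rose, including HAND2 by 4.13, GATA5 by 3.93 and the atrial myosin light chain MYL7 by 4.74 (camera adjusted p = 1.23e-15), while 11 of 14 somite genes fell (camera adjusted p = 2.00e-12). Amnion and trophoblast genes rose for 4 of 7, IGFBP3 by 4.40 and GABRP by 3.82 (camera adjusted p = 9.24e-06), and endothelium and blood genes for 2 of 8, the VEGF receptor KDR by 2.13 and the cadherin CDH5 by 1.95 (camera adjusted p = 4.45e-05). The calls of these 5 lists held with an estimated correlation. Neural crest genes rose for 4 of 9, TFAP2A by 4.37, TFAP2B by 2.12 and SOX10 by 1.68 (camera adjusted p = 4.80e-05, adjusted p = 0.0726 with an estimated correlation).

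Of 11 tested dermomyotome genes 2 rose, ALX4 by 3.60 and PAX7 by 1.51, and 3 fell, among them DMRT2 by -3.18 and SIX4 by -1.43. PAX3 at -0.98 was not called, and moved by -3.13 in 201B7 alone and by 1.17 in 1231A3 alone. It was called without SM 201B7 replicate 2 (-1.04), DM 201B7 replicate 2 (-1.20), SM 1231A3 replicate 1 (-1.02) or DM 1231A3 replicate 2 (-1.05). The list's median was -0.60 and camera placed it lower without a call (camera adjusted p = 0.438), whereas fry, which tests the members alone, placed it higher (fry adjusted p = 0.0105). EN1, SIM1, LBX1, MYF5 and MYOD1 lay below the filter. Notch pathway genes fell for 10 and rose for 1 of 17, DLL3 by -4.06 (camera adjusted p = 0.000262, adjusted p = 0.201 with an estimated correlation), and Wnt targets rose for 5 and fell for 1 of 13, LGR5 by 3.03 and NKD1 by 2.81 (camera adjusted p = 0.000399, adjusted p = 0.0831 with an estimated correlation). Hedgehog targets were lower for 2 and higher for 1 of 7, GLI1 by -1.93 (camera adjusted p = 0.136). Presomitic genes fell for 10 and rose for 2 of 16 (camera adjusted p = 8.73e-06, adjusted p = 0.141 with an estimated correlation). Skeletal myogenesis genes rose and fell for 1 each of 9, with ACTC1, a cardiac and fetal muscle actin, higher by 3.34 (camera adjusted p = 0.868).

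DM had 648 genes called higher and 855 lower than SM, 1503 in all, with 1494 moving the same way in both lines. The count was 2700 with a pseudocount of 0.1 and 709 when tested against a log2 change of 1. DM 201B7 replicate 2, the shallowest library, held HAND1 at 299 FPKM against 713 and 532 in its group.

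The step from SM to SCL asked which genes change over 72 h with hedgehog activation and BMP receptors blocked. PAX9, a paired box factor of the ventral somite and its sclerotome, rose from 0.365 ± 0.143 to 8.69 ± 8.33 FPKM (n = 6 each). PAX1 was called but reached only 1.27 ± 0.702 FPKM, and SOX9 stood at 13.5 ± 2.46 in SM and 17.7 ± 7.40 in SCL. The collagen COL3A1 rose to 491.5 ± 252.2 FPKM and the proteoglycan FMOD to 157 ± 29.9. PAX6, an eye and neural factor, reached 15.01 ± 12.03 FPKM.

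COL3A1 rose by 6.25 (SE 0.305, limma adjusted p = 1.53e-15; ENSG00000168542.13, chromosome 2, 188974320 to 189012746) and FMOD by 5.69 (SE 0.200, limma adjusted p = 1.70e-18; ENSG00000122176.10, chromosome 1, 203340628 to 203351758). The orphan receptors NR2F1 and NR2F2 rose by 4.98 and 3.46, SPX by 4.60, VGLL3 by 3.67, TIMP3 by 3.15 and PAX6 by 3.15 (SE 0.174, limma adjusted p = 2.165e-14; ENSG00000007372.20, chromosome 11, 31784779 to 31818062). The largest falls were CER1 at -5.83, WNT8A at -4.82, POU5F1 at -4.68 (SE 0.251, limma adjusted p = 1.22e-14), TRH at -4.38, SFRP5 at -4.29, PLA2G2A at -4.26, ALDH1A2 at -4.23 and NTS at -4.16.

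Of 11 tested sclerotome genes 4 rose, among them PAX9 by 2.44 (ENSG00000198807.12, chromosome 14, 36657568 to 36679715), SOX5 by 1.43 and PAX1 by 1.10 (camera adjusted p = 0.000662, adjusted p = 0.251 with an estimated correlation). Without SCL 201B7 replicate 1 the PAX1 change was 0.93 and no longer called, and without experiment 1 it was 0.94. SOX9 at 0.30, COL2A1 at 0.87 and TWIST1 at 0.67 were not called. Hedgehog targets had a median of 0.16 but a mean of -0.02, and 1 of 7 was called, HHIP, a hedgehog antagonist, at -1.37 (camera adjusted p = 0.489). Without SCL 201B7 replicate 2 the HHIP change was -0.98 and not called. PTCH1 at 0.25 and GLI1 at 0.24, standard readouts of the pathway that are named after their values were seen, were not called. PTCH1 stood at 67.9 ± 10.0 FPKM in SM and 81.5 ± 17.1 in SCL. BMP targets had a median of -0.03 (camera adjusted p = 0.809).

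Epithelial genes fell for 10 of 13, the cadherin CDH1 by -3.42 and the claudin CLDN7 by -2.86 (camera adjusted p = 4.05e-09), a call that held with an estimated correlation. Presomitic genes fell for 11 and rose for 1 of 16 (camera adjusted p = 1.57e-06, adjusted p = 0.118 with an estimated correlation), and pluripotency genes fell for 8 of 16 (camera adjusted p = 8.73e-06, adjusted p = 0.122 with an estimated correlation). Neural genes rose for 4 and fell for 2 of 10, SOX1 by 2.98 and TUBB3 by -1.40 (camera adjusted p = 0.0159, adjusted p = 0.296 with an estimated correlation). Dermomyotome genes rose for 2 of 11, EYA2 by 2.74 and MEOX2 by 2.66 (camera adjusted p = 0.0221, adjusted p = 0.288 with an estimated correlation). Somite genes fell for 3 and rose for 1 of 14, RIPPLY1 by -3.98 and TBX18 by 1.48 (camera adjusted p = 0.0511). Cartilage matrix genes fell for 4 and rose for 1 of 11, COL9A2 by -1.86 and COL9A1 by 1.19 (camera adjusted p = 0.371).

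SCL had 383 genes called higher and 814 lower than SM, 1197 in all, with 1190 moving the same way in both lines. The share higher was 32.0%, and 42.1% (546 higher and 750 lower) when each library was rescaled to the same sum. A pseudocount of 0.1 gave 2435 genes, and the test against a log2 change of 1 gave 469.

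The direct comparison of SCL with DM asked what separates the end points, which differed in time (72 h and 48 h) as well as in factors. Somite genes were higher in SCL: MEOX1 stood at 188 ± 54.6 FPKM against 6.55 ± 4.80 in DM, TCF15 at 71.7 ± 19.7 against 3.80 ± 2.2 and FOXC2 at 72.0 ± 25.9 against 5.63 (n = 6 each). BMP targets, lateral plate genes, epithelial genes and Wnt targets were lower in SCL. HAND1 was at 0.108 ± 0.189 FPKM in SCL and 328 ± 248 in DM. The hedgehog readout GLI1 was at 13.1 ± 8.01 FPKM in SCL and 1.86 ± 0.603 in DM.

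The genes most in favour of SCL were MEOX1 at 4.98 (SE 0.221, limma adjusted p = 1.09e-16), the T-box factors TBX1 at 4.80 (ENSG00000184058.12, chromosome 22, 19756703 to 19783593) and TBX18 at 4.27, the BMP antagonist NBL1 at 4.22, TCF15 at 4.02, BGN at 3.77, IQSEC3 at 3.53 and FOXC2 at 3.52. Those most in favour of DM were HAND1 at -7.80 (SE 0.220, limma adjusted p = 6.39e-21), PRRX1 at -6.89, MSX2 at -6.12, MYL7 at -5.91, BAMBI at -5.74, HOXB1 at -5.61, PRPH at -5.23 and RGS4 at -5.15.

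All 11 BMP targets (camera adjusted p = 1.49e-19) and 9 of 12 lateral plate and cardiac genes (camera adjusted p = 1.13e-16) were called lower in SCL. So were 11 of 13 epithelial genes, KRT8 at -3.82 and CDH1 at -3.53 (camera adjusted p = 2.96e-13), and 9 of 13 Wnt targets, DKK1 at -4.43 and NOTUM at -3.02 (camera adjusted p = 5.40e-11). Amnion and trophoblast genes were lower for 5 of 7 (camera adjusted p = 8.25e-08), endothelium and blood genes for 2 of 8 (camera adjusted p = 2.58e-05), and cartilage matrix genes for 4 of 11, COL9A2 at -3.58 and HAPLN1 at -3.29 (camera adjusted p = 0.000145). Somite genes were higher for 9 and lower for 2 of 14 (camera adjusted p = 1.46e-11). These 8 calls held with an estimated correlation.

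Dermomyotome genes were higher in SCL for 4 and lower for 2 of 11, with EYA2 at 3.33 and DMRT2 at 3.11, against ALX4 at -3.17 and PAX7 at -1.54 (camera adjusted p = 0.000885, adjusted p = 0.107 with an estimated correlation). Sclerotome genes were higher for 3 and lower for 2 of 11, PAX9 at 2.62 but SOX6 at -2.55 and UNCX at -1.17, with PAX1 at 0.81 not called except with a smaller pseudocount (2.32 with 0.1; camera adjusted p = 0.0134, adjusted p = 0.380 with an estimated correlation). Hedgehog targets were higher for 3 and lower for 2 of 7, GLI1 and, at 1.64, SFRP1 against HHIP at -1.60 and FOXF2 at -1.19 (camera adjusted p = 0.0471, adjusted p = 0.330 with an estimated correlation). The HHIP difference was 0.16 in 201B7 alone. Neural crest genes were lower for 5 and higher for 1 of 9, TFAP2A at -3.85 (camera adjusted p = 0.0131, adjusted p = 0.288 with an estimated correlation). Neural genes were higher for 2 of 10, PAX6 at 3.09 and SOX1 at 2.55 (camera adjusted p = 0.0134, adjusted p = 0.288 with an estimated correlation). Notch pathway genes were higher for 5 and lower for 1 of 17, HES5 at 2.94 (camera adjusted p = 0.0248, adjusted p = 0.417 with an estimated correlation). Intermediate mesoderm genes were lower for 2 of 5 (camera adjusted p = 0.0511).

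Between SCL and DM, 430 genes were called higher in SCL and 670 lower, 1100 in all, with 1096 in the same direction in both lines. The count was 2025 with a pseudocount of 0.1 and 521 when tested against a log2 change of 1.

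Genes enriched in a single stage over each of the other 5 numbered 248 in iPSC, 168 in PS, 195 in PSM, 112 in SM, 280 in DM and 119 in SCL. They are marks of stages chosen without a list. The 6 leading genes taken per stage included, in iPSC, TRIML2 (35.0 ± 6.02 FPKM, n = 6) and the receptor GPR176 (107 ± 10.8), and in PS DKK4 (591 ± 141), NODAL (302 ± 116) and the surface protein CD48 (23.8 ± 6.55). In PSM they included MSGN1 (389 ± 54.3), HES7 (156 ± 34.8) and WNT3A (46.7 ± 10.2), and in SM RIPPLY1 (207 ± 21.4), FOXL1 (39.8 ± 9.33) and PCDH8 (64.1 ± 47.7). Those of DM included HAND1 (328 ± 248), PRRX1 (269 ± 129) and RGS4 (56.3 ± 14.9), a regulator of G protein signalling, and those of SCL PAX6 (15.01 ± 12.03), BARX1 (12.2 ± 3.07), a homeobox factor, and EYA2 (32.0 ± 4.76). With adjusted p alone the numbers were 1720, 737, 727, 550, 760 and 682 in the same order.

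Part of each step differed between the lines. In PS, 201B7 held more of the streak factor MESP1 (32.4 ± 10.4 FPKM against 3.13 ± 2.09 in 1231A3, n = 3 each) and CYP26A1 (123 ± 9.22 against 28.8 ± 15.7), while 1231A3 kept more SOX2 (17.3 ± 6.95 against 2.47 ± 0.285). The step from iPSC to PS differed between the lines for 168 genes, 83 more positive and 85 more negative in 1231A3 (108 with a pseudocount of 0.1, 96 with a filter of 5 FPKM). MESP1 differed by -3.50 (SE 0.557, limma adjusted p = 0.000515; not called with a pseudocount of 0.1, at -4.82), CYP26A1 by -3.47 (SE 0.568, limma adjusted p = 0.000688) and SOX2 by 2.31 (SE 0.553, limma adjusted p = 0.0272). The SOX2 call was lost with a pseudocount of 0.1 and, at differences of 2.01 to 2.33, without iPSC 201B7 replicate 1, 2 or 3, PS 201B7 replicate 1 or 3, iPSC 1231A3 replicate 1 or 3, or PS 1231A3 replicate 3.

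At the step to PSM 466 genes differed (284 more positive in 1231A3), led by the endocytic regulator RAB17 at 2.99 (SE 0.439, limma adjusted p = 7.32e-05) and by GREB1L at -3.23 (SE 0.444, limma adjusted p = 3.26e-05). TDGF1 differed by 2.77, with 41.4 ± 22.7 FPKM in PSM 1231A3 and 6.38 ± 1.90 in PSM 201B7. Its call was lost without PSM 1231A3 replicate 1 (2.41) and with pseudocounts of 0.1 (2.93) and 0.5 (2.85). At the step to SM 663 genes differed (296 more positive in 1231A3). RIPPLY2, a repressor at segment borders, reached 18.8 ± 3.15 FPKM in 1231A3 and 1.86 ± 0.555 in 201B7, a difference of 4.26 between the steps (SE 0.343, limma adjusted p = 6.09e-09). SM MESP2 was at 29.99 ± 6.63 FPKM in 1231A3 and 4.22 in 201B7.

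In DM, PAX3 differed between the lines in the direction opposite to HAND1 and PRRX1. From SM to DM, PAX3 went from 47.0 ± 6.82 to 5.04 ± 3.43 FPKM in 201B7 and from 15.9 ± 2.174 to 37.3 ± 7.33 in 1231A3, a difference between steps of 4.30 (SE 0.345, limma adjusted p = 4.14e-09). HAND1 reached 514.5 ± 207.7 FPKM in DM of 201B7 and 141.5 ± 80.8 in DM of 1231A3 (difference between steps -1.89), and PRRX1 351.6 ± 115 against 186 ± 88.5 (-1.93). The neural crest factor SOX10 was at 14 ± 2.02 FPKM in DM of 1231A3 and 0.621 ± 0.733 in DM of 201B7. This step differed for 657 genes (267 more positive in 1231A3), and without DM 201B7 replicate 2 for 809.

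From SM to SCL 373 genes differed (150 more positive in 1231A3). LRP2, an endocytic receptor, differed by 2.91 (SE 0.405, limma adjusted p = 4.51e-05), the BMP effector ID3 by 2.79 (SE 0.365, limma adjusted p = 1.98e-05) and HTRA3 by -3.08 (SE 0.231, limma adjusted p = 1.60e-09). PAX6 reached 25.5 ± 4.85 FPKM in SCL of 1231A3 and 4.55 ± 3.18 in SCL of 201B7, and its steps differed by 2.166. PAX9 was at 14.2 ± 9.12 FPKM in SCL of 201B7 and 3.23 ± 0.885 in SCL of 1231A3. Between SCL and DM 458 genes differed by line (248 more positive in 1231A3), including ID2 at 2.90 and HHIP at -3.52. Tested against a log2 change of 1, the 6 line-dependent counts were 3, 3, 16, 45, 11 and 12. All 6 also shrank without experiment 1 (12 libraries fewer), to 47, 162, 239, 337, 92 and 150 in the order given. The calls of MESP1, SOX2, TDGF1 and HHIP were then lost, at -3.69, 2.43, 2.49 and -2.77.

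**Figure D3:**
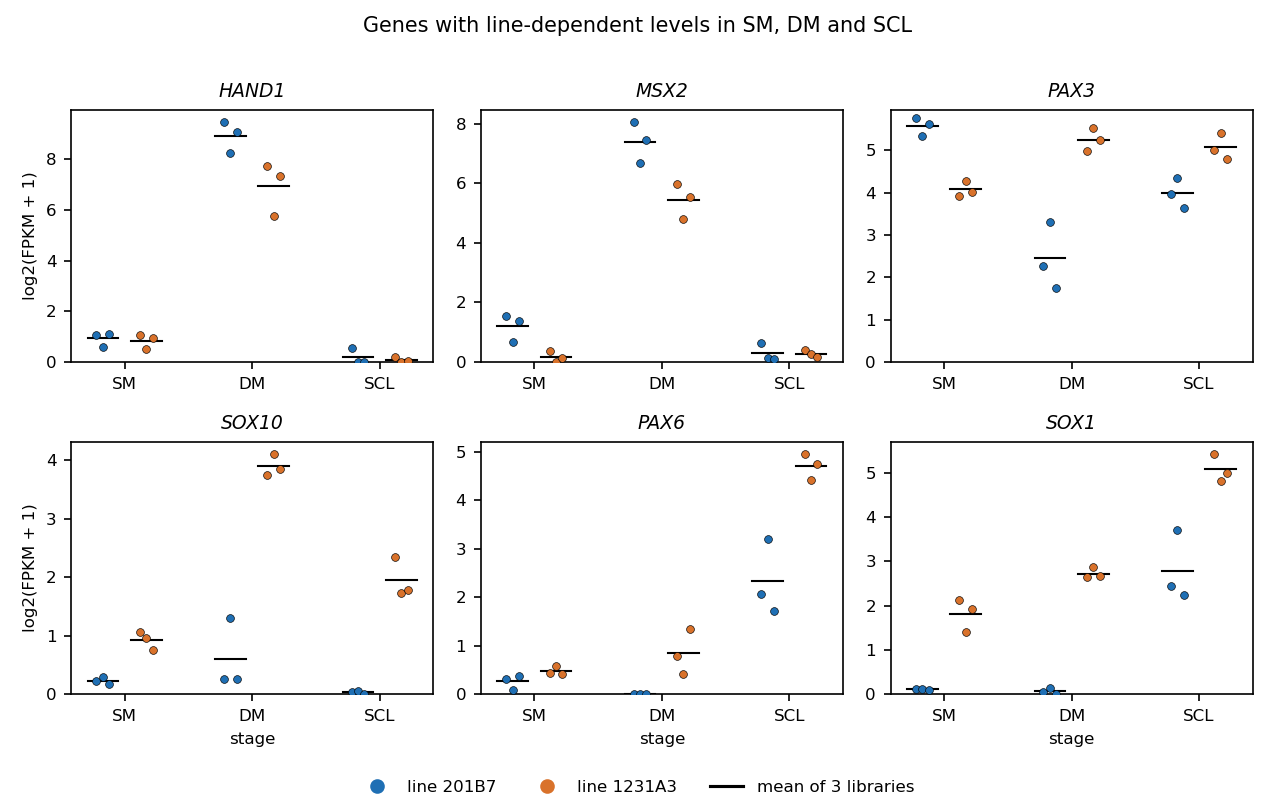
Levels of HAND1, MSX2, PAX3, SOX10, PAX6 and SOX1 in SM, DM and SCL, log2(FPKM + 1) on the vertical axis and stage on the horizontal axis; each point is 1 library (blue 201B7, orange 1231A3) and each bar the mean of 3. In DM, PAX3 and SOX10 lay higher and HAND1 and MSX2 lower in 1231A3.

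Averaged over the stages, 226 genes were higher and 147 lower in 1231A3 than in 201B7, 373 of 18644. This comparison treated the libraries of a line as independent, although each line had 3 experiments and part of their libraries deviated together across stages. Its p-values and counts may therefore be overstated. The imprinted gene NNAT was higher in 1231A3 by 6.14 (SE 0.247, limma adjusted p = 1.07e-17; ENSG00000053438.8, chromosome 20, 37521206 to 37523693), with 633 ± 78.2 FPKM in SM of 1231A3 (n = 3) against 0.0462 in SM of 201B7. MEG3, an imprinted non-coding RNA, was lower by -5.34 (SE 0.149, limma adjusted p = 2.15e-21; ENSG00000214548.14, chromosome 14, 100779410 to 100861031), with 88.7 ± 14.7 FPKM in iPSC of 201B7 and 0.152 in iPSC of 1231A3. NLRP2, a maternal-effect gene, differed by -4.65, CEBPZOS by -4.32 and PKIB by -3.77. The pseudogenes MTND1P23 (7.83), MTND4P12 (6.11) and MTCO2P12 (5.74) share reads with mitochondrial genes and are uncertain. In PSM 201B7 replicate 3 NLRP2 and MEG3 lay between the lines, MEG3 at 11.2 FPKM against 21.4 to 374 in the other libraries of 201B7, and without it 367 genes differed. The count was 1098 with a pseudocount of 0.1 and 133 when tested against a log2 change of 1.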

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

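Tests chosen only after the result was seen were those of line genes in PSM 201B7 replicate 3, of presomitic genes in PS 1231A3 replicate 2 and of lateral plate and neural crest genes in DM, and the exchanges of stage or line names, except those made with each gene's mean line difference removed. The name filter at first missed 2 entries of X inactivation genes, which were removed after the results had been seen, and the number of called genes stayed the same in every comparison.

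In PSM 201B7 replicate 3, some genes that separate the lines lay between them, FZD10 at 12.7 FPKM (0 to 0.174 in the 17 other libraries of 201B7) and NLRP2 at 5.58 (13.2 to 71.2), whereas ZFP42 at 30.8 lay above both lines (0 to 1.89, and 11.8 to 15.6 in PSM 1231A3) and MTND1P23 was at 11.6 (3.63 to 10.7, and 2314 to 3093). On the log scale the median position of 61 line genes was 27.5% of the way to 1231A3. The other PSM 201B7 libraries gave -18.5% (49 genes) and -7.7% (54 genes). Each library was set against the mean of the others of its group. The negative values thus partly follow from replicate 3 and are no independent reference. Because such a position is no share of RNA, a test for 1 common share, on a stricter set of line genes, was chosen after this result. RNA or cells of 1231A3 at 1 share would place most of the 17 line genes near their median share of 23.1%, but 5.9% lay within 1.5 times of it (60.8% in computed mixtures; quartiles 9.4% and 49.4%), which argues against it. A label exchanged with a PSM 1231A3 library was argued against by the correlations, higher with the library's own group by 0.021 (0.977 against 0.955). Another passage, subclone or culture state of 201B7 may account for it, and no biological explanation was tested.

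In PS 1231A3 replicate 2, presomitic genes were higher than in the other two libraries of the group, with MSGN1 at 44.2 FPKM against 4.71 and 3.31 and HES7 at 18.5 against 0.280 and 0.581. Over 23 genes at 20 FPKM or more in PSM and 20 times lower in the other PS libraries, 21 lay above both, at a median share of 11.4% of their PSM level (quartiles 7.9% and 16.3%). Average PSM cells or RNA at 1 share would place most of the genes near that median, and 47.8% lay within 1.5 times of it. Single genes ranged widely, with HOXB2 at 31.6%, KCNK17 at -1.3% and RNY3P15 at 240.9%. The scatter of whole PSM replicates gave 91.3%, but no mixtures at so low a share were computed, so this test could not decide. A library labelled PS that holds the PSM sample was argued against by the correlations, higher with its own group by 0.021 (0.978 against 0.958). Presomitic cells of another profile than the PSM libraries, or progress toward PSM that was uneven between genes, may account for it and were not tested.

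In DM, lateral plate and cardiac genes were lower in 1231A3 than in 201B7 (median -1.24, 8 of 12 lower in every library), while neural crest genes were higher (median 1.88, 7 of 9 higher in every library). Chance gives 10% either way if the lines do not differ, and the share over all genes was not computed. Scaling of the libraries was argued against, since both medians stayed at least 1.24 from 0 under the 3 other scalings run. The limit for this test was set after those medians were known. A larger share of all non-somite cells in 201B7 would have moved both lists alike. The lists lay apart by 3.12, but that is the pattern itself and no separate test. A weaker BMP response in 1231A3 may account for the lateral plate part, since 8 of 11 BMP targets were lower in every library of DM 1231A3, though 6 of 11 were so in SM, before the BMP4 of this step. Neural crest cells as the only source of PAX3 in DM of 1231A3 cannot be told apart from dermomyotome cells, since MEOX1 was higher there too, by 1.81, at a low level (10.1 ± 2.60 FPKM against 3.04 ± 3.72, n = 3 each). A genetic or epigenetic difference between the lines stays open and was not tested.

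A library stood far from the other 5 of its stage in 2 of 60 tests (beyond the 95% critical value, which chance passes about 1 in 20 times): the mean of the somite list in PS 1231A3 replicate 2, with a ratio of gap to range of 0.696, and the FPKM sum of DM 201B7 replicate 1, with 0.643.

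The genes named for line-dependent steps were taken up because the difference between the lines was itself tested. From iPSC to PS, the step in 1231A3 exceeded that in 201B7 by 2.77 for TMEM132C, 2.38 for HES3, 2.31 for SOX2 and 2.28 for MEG9. It fell short for MESP1 (-3.50), CYP26A1 (-3.47), NPTX1 (-2.83) and FGF17 (-2.60). From PS to PSM the difference was 2.99 for RAB17, 2.86 for MESP1, 2.77 for FGF17 and 2.77 for TDGF1. It was -3.23 for GREB1L, -3.08 for S100A1, -3.08 for ECM1 and -2.84 for CLDN11. From PSM to SM it was 4.62 for NNAT, 4.26 for RIPPLY2, 4.14 for RNU6-890P and 4.09 for PCDH19. TSPAN7 (-3.32), VAT1L (-3.26), RNU4-78P (-2.75) and CSMD1 (-2.66) went the other way. From SM to DM it was 4.30 for PAX3, 3.97 for TMEM110-MUSTN1, 3.88 for MUSTN1, which overlaps it, and 3.61 for CYP1B1. Negative differences were those of NNAT (-3.71), MESP2 (-3.70), IGFBP3 (-3.56) and HTRA3 (-3.56). From SM to SCL it was 2.91 for LRP2, 2.79 for ID3 and 2.77 for CYP26C1. ESRG (-3.21), RIPPLY2 (-3.16), ADAMTS15 (-3.08) and HTRA3 (-3.08) were lower. Between SCL and DM it was 3.34 for MAB21L2, 3.19 for IGFBP3, 3.16 for CLSTN2 and 2.90 for ID2. SNORA7A (-6.48), SNORA55 (-4.68), HHIP (-3.52) and MT1E (-3.31) went the other way. The short RNAs RNU6-890P, RNU4-78P, SNORA7A and SNORA55 are poorly caught by a poly(A) kit and are uncertain.

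Of the 96 largest rises and falls the rule took, 23 also differed by line. Besides NPTX1, SOX2 and TDGF1, given above, they were SORBS2 from iPSC to PS (1.17), and DKK4 (1.25), NODAL (1.78), CYP26A1 (1.96) and CALCR (1.03) from PS to PSM. From PSM to SM they were CER1 (2.08), PAX3 (-1.61), IGFBP5 (1.85), SPRY4 (1.02) and PCSK1 (1.44). From SM to DM they were PRRX1 (-1.93), HAND1 (-1.89), RIPPLY1 (1.00) and MEOX1 (2.01). PAX6 (2.166) and PLA2G2A (-2.81) followed from SM to SCL. Between SCL and DM they were MEOX1 (-2.50), HAND1 (1.87), MSX2 (1.96) and RGS4 (1.30).

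Each count of called genes was set against 100 splits of the same libraries, the real one included. With stage names exchanged within each line, only the real split, 1 of 100, gave a count as large in each of the 6 stage comparisons. That is the smallest share 100 splits can give. An exchange also moves the differences between stages into the spread within groups, which lowers the other counts. These splits show that the real names gave the most genes, but they do not by themselves exclude chance. The highest other counts were 696 (real 1356) for PS against iPSC, 844 (1424) for PSM against PS, 844 (1533) for SM against PSM, 865 (1503) for DM against SM, 632 (1197) for SCL against SM and 692 (1100) for SCL against DM. For the lines it was 44 (373, 1 of 100). Line names were exchanged in each stage separately, which breaks up any deviation shared by the libraries of an experiment. For genes enriched in iPSC, PS, PSM, SM, DM and SCL it was 1, 1, 4, 1, 1 and 0 (real 248, 168, 195, 112, 280 and 119, each 1 of 100). The same limit holds for the lines and the enriched genes.

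For the line-dependent steps, exchanging line names within each stage gave as many genes in 14 of 100 splits for PS against iPSC, 12 for PSM against PS, 11 for SM against PSM, 10 for DM against SM, 10 for SCL against SM and 11 for SCL against DM, so these splits could not exclude chance. Their highest other counts were 1359, 2828, 1365, 1430, 2395 and 2557, several times most of the real counts (168, 466, 663, 657, 373 and 458). That points to a structure of the samples: exchanging the names in 1 stage turns differences between the lines into differences between steps. With each gene's mean line difference over both stages removed, the real split alone, 1 of 100, gave as many in each step, with highest other counts of 11, 243, 93, 103, 93 and 364. The removed difference was computed with the real line names, which favours the real split. These splits therefore cannot exclude chance for the line-dependent counts either.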

How the results depend on the processing

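Leaving out experiment 1, keeping protein-coding genes only and recomputing the similarity of libraries under other settings were chosen after the data were seen. For the genes and lists named, 10091 of 10592 values under another setting kept their direction and side of the threshold, 420 lost the call, 73 gained one and 8 reversed. Except where stated, the cause was not tested.

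A pseudocount of 0.1, which widens differences among low values, gave 2545, 2686, 2768, 2700, 2435 and 2025 genes for the 6 stage comparisons in the order of the report (with 1: 1356, 1424, 1533, 1503, 1197 and 1100). It gave 108 line-dependent genes for PS against iPSC (168), 1098 between the lines (373), and 427, 259, 183 and 182 genes enriched in iPSC, PS, SM and SCL (248, 168, 112 and 119). Within groups r was 0.952 with it and 0.971 with a pseudocount of 0.5 (0.976). A filter of 5 FPKM, which tests fewer genes, gave 96 line-dependent genes for PS against iPSC and r 0.968, and no filter gave r 0.986.

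Adjusted p alone, without the log2 threshold, called 6790, 7349, 7698, 6625, 6526 and 4677 genes, 708 line-dependent ones for PSM against PS, 1398 for SM against PSM, 1022 for DM against SM and 563 for SCL against SM, and 7591 between the lines. Enriched genes then numbered 1720, 737, 727, 550, 760 and 682. The stricter treat test against a log2 change of 1 called 599, 576, 668, 709, 469 and 521 genes. It left 3, 3, 16, 45, 11 and 12 line-dependent genes, 133 between the lines, and 97, 82, 92, 51, 168 and 49 enriched ones.

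Without experiment 1, with 12 libraries fewer, line-dependent genes numbered 47, 162, 239, 337, 92 and 150. In 201B7 alone ACTC1 changed by -0.11 from PSM to SM (1.03 in the fit of both lines), RIPPLY2 by -0.46 (1.67), and HHIP differed by 0.16 between SCL and DM (-1.60). In 1231A3 alone PAX3 rose by 1.17 from SM to DM (-0.98), and SOX9 and GLI1 differed by -0.043 and -0.079 between SCL and SM (0.30 and 0.24, neither called). Without experiment 1 GLI1 differed by -0.097. Of 210 list tests, 99 passed with camera, 26 with an estimated correlation, 158 with fry and 184 with fry for either direction. The dermomyotome list in DM against SM reversed from lower with camera (adjusted p = 0.438) to higher with fry (adjusted p = 0.0105). Fry compares members with no other genes.

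With a replicate block of line by experiment, the stage comparisons gave 1362, 1426, 1531, 1505, 1201 and 1098 genes, and enriched genes numbered 250, 168, 195, 112, 280 and 119. With a block of experiment within each line, line-dependent genes numbered 229, 531, 755, 747, 433 and 557. With a block of experiment number, 374 genes differed between the lines. That block removes only deviations that both lines share under the same number. Deviations of an experiment within 1 line stayed in the comparison of the lines. No count moved by over 1.5 times. Experiment numbers paired the libraries in part: 47 of 90 pairs with the same number deviated together (r over 0.1), and 29 of 36 libraries were closest to their own number. In 201B7 all 15 pairs of experiment 1, all 15 of experiment 2 and 2 of 15 of experiment 3 deviated together. In 1231A3 these were 9, 5 and 1 of 15. The first component of the residuals (20.7%) set experiment 1 apart in most groups. The main fit did not model these shared deviations.

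With each library left out in turn, counts ranged from 1331 to 1396 for PS against iPSC, 1381 to 1481 for PSM against PS, 1474 to 1580 for SM against PSM, 1465 to 1551 for DM against SM, 1157 to 1232 for SCL against SM and 1095 to 1159 for SCL against DM. Line-dependent genes ranged from 124 to 198, 364 to 567, 534 to 866, 559 to 809, 302 to 415 and 359 to 632, genes between the lines from 354 to 381, and enriched genes from 236 to 273, 157 to 179, 191 to 213, 107 to 119, 264 to 298 and 116 to 128. Of 7524 values of named genes, 7401 kept their side of the threshold, 119 lost the call, 4 gained one (PAX3 in DM against SM) and 0 reversed. Under other scalings the median change of all genes lay between -0.023 and 0.087.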

Other observations

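Line differences of whole lists within a stage were chosen for description after the data were seen, whereas the lists and their tests were not.

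Cholesterol synthesis genes fell for 10 of 14 from SM to DM (median -1.24, camera adjusted p = 1.99e-08, adjusted p = 0.0832 with an estimated correlation) and for 11 of 14 from SM to SCL (median -1.37, camera adjusted p = 2.15e-10, adjusted p = 0.0495 with an estimated correlation). HMGCS1, an early enzyme of the pathway, went from 611.8 ± 128 FPKM in SM to 154 ± 57.7 in DM and 155 ± 38.8 in SCL (n = 6 each), and INSIG1, its sterol sensor, changed by -2.06 and -1.89. Oxidative phosphorylation genes had medians of -0.42 in DM (camera adjusted p = 4.78e-06, adjusted p = 0.239 with an estimated correlation) and -0.40 in SCL (camera adjusted p = 4.22e-05, adjusted p = 0.288 with an estimated correlation), without a member that passed the log2 threshold. Mitochondrially encoded genes had medians of -0.77 in DM (camera adjusted p = 6.23e-05) and -0.66 in SCL (camera adjusted p = 5.49e-05), each with adjusted p = 0.311 with an estimated correlation. Glycolysis and hypoxia genes fell for 2 of 13 from SM to SCL, LDHA by -1.59 (camera adjusted p = 0.000620, adjusted p = 0.242 with an estimated correlation), and p53 and stress genes rose for 4 of 12 from iPSC to PS, CDKN1A by 1.28 (camera adjusted p = 0.0173, adjusted p = 0.288 with an estimated correlation). Proliferation genes had a median of -0.50 from iPSC to PS (camera adjusted p = 0.000173, adjusted p = 0.132 with an estimated correlation). Ribosomal protein genes had medians between -0.004 and 0.087 over the 6 comparisons (camera adjusted p 0.200 to 0.982).

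From PS to PSM the enzyme that makes retinoic acid rose and one that degrades it fell, with 4 of 12 retinoic acid genes higher and 1 lower (camera adjusted p = 0.0221, adjusted p = 0.288 with an estimated correlation). In SCL 4 rose and 5 fell, CYP26C1 by 3.69 and CRABP1 by 2.95 against ALDH1A2 by -4.23, and the list had a median of -0.54 and a mean of 0.03 (camera adjusted p = 0.850). HOX groups 6 to 9 rose for 2 of 4 in DM, HOXB6 by 2.49 (camera adjusted p = 0.00453, adjusted p = 0.166 with an estimated correlation). HOX groups 1 to 5 rose for 5 and fell for 1 of 13 there, HOXB1 by 3.35, with a median of -0.40 and a mean of 0.39 (camera adjusted p = 0.764). Cartilage matrix genes rose for 4 and fell for 1 of 11 in DM, HAPLN1 by 2.57 (camera adjusted p = 0.00316, adjusted p = 0.0887 with an estimated correlation), and fibroblast and tendon genes rose for 6 and fell for 1 of 12 in SM, COL1A2 by 2.32 (camera adjusted p = 0.0193, adjusted p = 0.311 with an estimated correlation).

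Lists also differed between the lines within a stage. Members are counted when all 3 libraries of 1231A3 lay on 1 side of all 3 of 201B7. Chance gives this for 10% of genes counting either side, if the lines do not differ. That is a low reference, since 7591 of 18644 tested genes differed between the lines at a limma adjusted p under 0.05, averaged over the stages. The share of all genes separated within a stage was not computed, so the counts are not shown to be particular to a list. In PS 12 of 15 primitive streak genes were lower in 1231A3 (median -0.90). In PSM 11 of 13 epithelial genes were higher (median 1.81), 12 of 16 pluripotency genes were higher (median 0.67) and 10 of 13 genes of HOX groups 1 to 5 were lower (median -0.91). In SM 10 of 13 epithelial genes (median 1.35) and 11 of 13 glycolysis and hypoxia genes (median 1.16) were higher. So were 12 of 16 pluripotency genes (median 0.59) and 13 of 19 proliferation genes (median 0.46) in SM. Presomitic genes were higher there for 10 and lower for 1 of 16 (median 0.93). Somite genes were lower for 6 and higher for 1 of 14 (median -0.38). In DM 10 of 16 pluripotency genes (median 0.58) and 8 of 13 epithelial genes (median 1.36) were higher, the neural list was higher for 6 and lower for 1 of 10 (median 0.83), 7 of 12 fibroblast and tendon genes were lower (median -1.25) and 3 of 11 dermomyotome genes were higher (median 0.50). BMP targets were lower for 6 and higher for 2 of 11 in SM (median -0.50). In SCL the sclerotome list was lower for 6 and higher for 1 of 11 (median -0.71), and the neural list higher for 6 and lower for 2 of 10 (median 0.98), with SOX1 at 33.6 ± 7.80 FPKM in 1231A3 and 6.72 ± 4.62 in 201B7 (n = 3 each). These values rest on 3 experiments per line and were not tested as lists.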
